A study of Mus musculus with 8 samples.

How the data were processed

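RNA was measured in 8 libraries of mouse lineage-depleted bone marrow cells, which are blood stem and progenitor cells left after removal of mature cells, grown in culture with cytokines. Per the labels, 4 libraries came from wild-type (WT) cells and 4 from cells with a floxed Alkbh5 gene and Vav-iCre, a recombinase expressed in blood cells. In each genotype 3 libraries came from cells fed 100 µM of the nucleoside 4-thiouridine (s4U) for 2 h and 1 from cells labelled as having received no agent. Per the labels' protocols, total RNA went through TimeLapse chemistry, which recodes incorporated s4U so that it is read as C, and libraries were made with a stranded total RNA kit for low inputs.

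Each deposited file holds read counts per gene for 1 library, as whole numbers that were not normalized. Per the submitters' processing notes, cutadapt, HISAT2, Picard, HTSeq, STAR and DESeq2 were used with the mm10 and GRCm38 builds. Their versions, roles and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. Each file lists 27710 genes and 928 entries that name no gene, which include reads in no gene and in several genes. Reads in no gene made up between 37.6% and 52.1% of all counts per library and, like reads in several genes, stayed out of library sizes and tests. The remaining totals ranged from 5723245 to 8615997 counts. Counts of converted bases were not analysed here, so no RNA half-life was estimated. Of the gene symbols, 27070 matched GENCODE M21, from which coordinates (GRCm38), gene classes and GC content were taken.

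Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default low-count filter, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. The genotype contrast used the 6 fed libraries. The s4U contrast and the genotype by s4U interaction used all 8. The standard error of a log2 fold change was its size divided by the root of the F statistic. CPM values of Alkbh5, Ogdh, Nefh and the s4U contrast were TMM-scaled over 8 libraries, and those of list members in the genotype contrast over the 6 fed libraries. Of 29 gene lists for metabolism, RNA methylation, stress programs and cell types, 28 had at least 3 tested members. Genes encoded by mitochondrial DNA formed the list without any. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether members move on balance in 1 direction. Groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Alkbh5 and Ogdh, the latter from knowledge of the study, in every library. It took up to 8 genes per direction past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes and pseudogenes, or all genes that passed where fewer than 8 did. For each list it took up to 3 members past the threshold, or the 2 members with the smallest p as values where the list passed and no member did.

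Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples only. No pair of libraries agreed within sampling noise: the chi-square statistic per gene was at least 3.12. Replicate numbers come from the labels. Deviations from the group means correlated across genes between same-numbered WT and Alkbh5-deficient libraries, with r = 0.68, 0.29 and 0.19 for numbers 1, 2 and 3, so fits with the replicate number as a block were computed beside the others. The pairing by number is less sure for numbers 2 and 3, since WT replicate 2 and Alkbh5-deficient replicate 3, and the reverse, correlated at 0.35. Replicate 2 of both genotypes had Xist RNA and 0 counts of the Y-linked Ddx3y, and replicates 1 and 3 had Ddx3y and at most 2 counts of Xist. Both unlabelled libraries had both, with 9147 and 8770 counts of Xist and 299 and 511 of Ddx3y, so each held RNA of both sexes. Replicate 2 of each fed group thus came from another animal than replicates 1 and 3, and whether replicates 1 and 3 came from separate animals is not given in the sources used here.

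Alternatives were RLE size factors, no low-count filter, a filter of 1 CPM, DESeq2 1.42.0, removal of small RNA genes, a threshold of 0.1, the replicate block, the additive fit over 8 libraries, each library left out, and fits within a genotype. Limma voom with sample weights, DESeq2 with the replicate block, a GC correction by lowess with a span of 0.3, removal of the ribosomal-repeat genes Gm26917 and Gm42418, and removal of both libraries of a pair were chosen after seeing the data. GC content was known for 99.1% of the genes tested between genotypes. Processed pseudogenes were aligned to protein-coding transcripts with BLAST+ 2.17.0. The tests were run on simulated data with 200 changed genes, 50 of each size. The changed genes were drawn only from genes above a minimum expression level, so the shares do not cover weakly expressed genes. Replicate effects and correlation between genes were not simulated. The shares with the replicate block therefore do not show what the block recovers where replicates differ. For the genotype contrast over 13342 genes, 96% and 94% of genes changed by -2 and 2 log2 units were recovered, and 34% and 32% of those changed by -1 and 1, with 6 false calls among 134. With the replicate block the shares were 98%, 100%, 72% and 72% in the same order, with 21 false calls among 192. These shares for the genotype contrast may overstate recovery in the real fed libraries. There, 151 genes had an unadjusted edgeR p under 0.05, or 353 with the replicate block, where 667 would be expected by chance. For the s4U contrast over 14988 genes the shares were 92%, 94%, 52% and 26% in the same order. For the interaction over the same genes, 0% of the genes changed by -2 and 2% of those changed by 2 were recovered. Intervals given for counts and shares are exact 95% intervals and cover counting error only.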

Results

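ALKBH5 removes the methyl group of N6-methyladenosine (m6A) in RNA. The series, by its title, concerns the stability of metabolic transcripts in cells without it, and it used s4U feeding to mark RNA made during the labelling time. Gene counts per library totalled 7193176 for the unlabelled WT library and 6338915, 8404565 and 5723245 for WT fed replicates 1 to 3. They totalled 8615997 for the unlabelled Alkbh5-deficient library and 7172562, 7183882 and 7708983 for fed replicates 1 to 3. Comparisons were made between genotypes, between fed and unlabelled libraries, and between the genotype differences with and without s4U.

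Alkbh5 RNA was nearly absent from every library labelled as Alkbh5-deficient. The gene (ENSMUSG00000042650.3, chromosome 11, 60536381 to 60558512, plus strand) had 1166, 1479 and 1061 counts in WT fed replicates and 0, 1 and 1 counts in the deficient ones. WT fed libraries averaged 190 ± 18.1 CPM (SD, n = 3). The pooled fed ratio was 0.0489% of WT, with a counting interval of 0.00592% to 0.177%. In the unlabelled pair, 1263 WT counts stood against 1 count, a ratio of 0.0679% (0.00172% to 0.379%).

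The question of the genotype comparison was which transcripts differ in level once ALKBH5 is lost. Alkbh5 was the 1 gene of 13342 past the threshold in the fed libraries (edgeR quasi-likelihood test, adjusted p = 7.91e-06), and 0 genes were higher. By edgeR 151 genes had an unadjusted p under 0.05, or 353 with the replicate block, where 667 would be expected by chance, and DESeq2 called 2 genes, both lower. Ogdh, which encodes the E1 subunit of the 2-oxoglutarate dehydrogenase complex of the tricarboxylic acid (TCA) cycle, had the second-smallest p. Ogdh (ENSMUSG00000020456.17, chromosome 11, 6291633 to 6356642, plus strand) averaged 234 ± 21.7 CPM in WT fed libraries and 102 ± 11.7 CPM in Alkbh5-deficient fed libraries (SD, n = 3 each). Single libraries lay at 239, 210 and 252 CPM against 93.1, 115 and 97.4 CPM, so the groups did not overlap. The same held for 757 of the 13342 tested genes (5.67%), where 10% would be expected by chance. The log2 fold change of Ogdh was -1.20 ± 0.16 (SE), or 43.5% of WT, with unadjusted p = 5.24e-05 and adjusted p = 0.349 over all genes in edgeR. Adjusted over the list alone, Ogdh passed in the TCA cycle list and in the list for 2-oxoglutarate metabolism, each with 19 tested members (adjusted p = 0.000995 in both, edgeR). Both values come from the same unadjusted p, and Ogdh was chosen from knowledge of the study, so they give no separate support. Over all genes, Ogdh passed with DESeq2 (adjusted p = 7.57e-06), with DESeq2 and the replicate block (adjusted p = 5.05e-06), without the low-count filter (adjusted p = 0.00894), and with limma voom weights and the block (adjusted p = 0.00234). Over its 21 alternatives the adjusted p ranged from 5.05e-06 to 1.00 and the log2 fold change from -1.30 to -1.05.

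**Figure D1:**
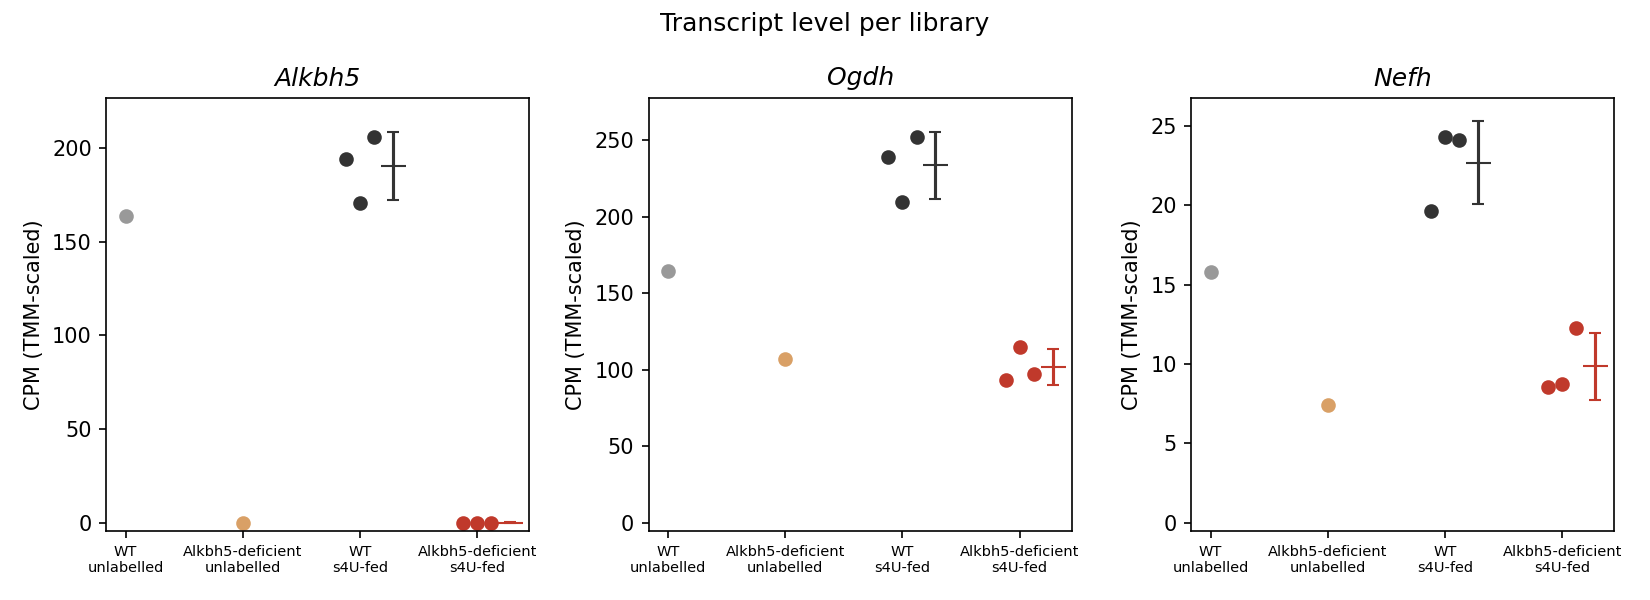
TMM-scaled CPM of Alkbh5, Ogdh and Nefh in each of the 8 libraries, with 1 point per library and, beside each fed group, its mean and SD (n = 3). WT fed libraries lie between 210 and 252 CPM of Ogdh and Alkbh5-deficient fed libraries between 93.1 and 115 CPM.

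Nefh, the neurofilament heavy chain gene, had the third-smallest p and was chosen after its values were seen. Nefh (ENSMUSG00000020396.8, chromosome 11, 4938754 to 4948064, minus strand) averaged 22.7 ± 2.64 CPM in WT fed libraries and 9.85 ± 2.09 CPM in Alkbh5-deficient fed libraries (SD, n = 3 each). Its log2 fold change was -1.20 ± 0.23 (SE), with an edgeR adjusted p of 1.00, and of its 21 alternatives it passed with voom weights and the block alone (adjusted p = 0.0405). The gene starts 1.35 Mb from the start of Ogdh, and Alkbh5 lies 54.2 Mb beyond Ogdh on the same chromosome. The 22 tested genes between Nefh and Ogdh had a median log2 fold change of -0.11 in the fit with the replicate block. In that edgeR fit 0 of them passed the threshold, and neither did Ogdh or Nefh (adjusted p = 0.359 and 0.793). The smallest p among the 22 belonged to lower genes, Ddx56 at -0.54 ± 0.17 and Pold2 at -0.40 ± 0.17 (SE, unadjusted p = 0.0116 and 0.0483).

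**Figure D2:**
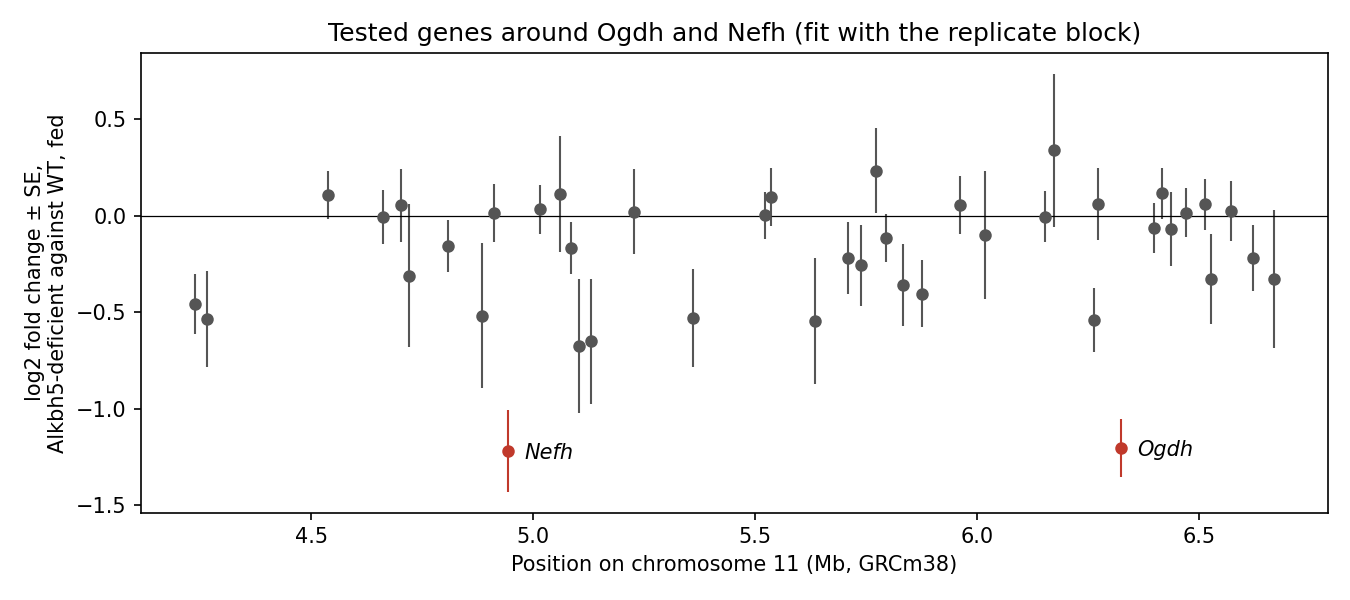
Log2 fold change ± SE (Alkbh5-deficient against WT, fed libraries, fit with the replicate block) of tested genes against their position on chromosome 11 in Mb. Nefh and Ogdh, in red, lie below the genes between them, which range from -0.67 to 0.34.

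Among the fixed gene lists, 6 were lower and 2 higher in Alkbh5-deficient fed libraries by camera with the preset correlation, while 0 members of these lists passed the threshold singly. Immediate early genes, transcription factors and regulators induced within minutes of stimulation, had 30 of 35 members with a negative log2 fold change and a median of -0.22 (adjusted p = 2.66e-07, and adjusted p = 0.493 with an estimated correlation). Egr1 averaged 528 ± 96.2 CPM in WT and 371 ± 27.3 CPM in Alkbh5-deficient fed libraries, and Fosb 217 ± 14.7 against 168 ± 15.2 CPM (SD, n = 3 each). Interferon response genes had 24 of 27 members with a negative value and a median of -0.38 (adjusted p = 1.12e-06, and adjusted p = 0.493 with an estimated correlation). Ifit1 averaged 5.88 ± 2.28 against 2.49 ± 0.88 CPM and Oasl1 12.6 ± 4.68 against 6.69 ± 1.87 CPM. T and NK cell markers had 13 of 14 members with a negative value and a median of -0.39 (adjusted p = 0.00324, and adjusted p = 0.814 with an estimated correlation), with Gzma at a log2 fold change of -1.10 ± 0.48 (SE) and Gata3 at -0.54 ± 0.34. NF-kB and inflammation genes had a median of -0.13 over 18 members (adjusted p = 0.0415, and adjusted p = 0.493 with an estimated correlation), with the chemokine gene Ccl4 at -0.53 ± 0.21 (SE) and Nfkbiz at -0.36 ± 0.23. With an estimated correlation 0 of the 28 lists passed, and with fry 0 lists passed, with a smallest adjusted p of 0.777. Immediate early and interferon genes passed with any single fed library left out. Between same-numbered libraries the immediate early median was -0.20, -0.09 and -0.54, the last with WT replicate 3. In that library the ribosomal-repeat gene Gm26917 took 14.2% of counts, against 6.33% to 8.34% in the other 7, and the list passed without that library (adjusted p = 5.99e-05). The medians between same-numbered libraries were -0.79, -0.15 and -0.14 for T and NK cell genes and, for NF-kB genes, 0.04, -0.32 and -0.13. The T and NK cell list was lost without WT replicate 2 or Alkbh5-deficient replicate 1, and the NF-kB list without replicate 2 of either genotype.

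Nuclear genes of oxidative phosphorylation had a median of -0.10, with 51 of 73 members negative (camera adjusted p = 0.0191, and adjusted p = 0.814 with an estimated correlation). Between same-numbered libraries the median was 0.01, -0.03 and -0.15. Their members with the smallest p went opposite ways, Ndufb4 at a log2 fold change of 0.85 ± 0.44 (SE) and Cox6a1 at -0.42 ± 0.23. TCA cycle genes had a median of -0.08, with 13 of 19 members negative (camera adjusted p = 0.0415, and adjusted p = 0.504 with an estimated correlation). The TCA list rested on Ogdh: without it the remaining 18 members gave an adjusted p of 0.191 and a median of -0.06. Mdh2, for mitochondrial malate dehydrogenase, had a log2 fold change of -0.35 ± 0.22 (SE). With the replicate block the TCA list no longer passed (adjusted p = 0.0610). Both lists were lost without WT fed replicate 1 or without Alkbh5-deficient fed replicate 2 or 3. Cholesterol synthesis genes had a median of 0.16, with 17 of 22 members positive, and replication-dependent histone genes a median of 0.11, with 47 of 66 positive (camera adjusted p = 0.0415 for both, and adjusted p = 0.814 and 0.823 with an estimated correlation). Nsdhl, a sterol synthesis enzyme gene, was at 0.70 ± 0.48 (SE), Stard4, a cholesterol transport gene, at 0.26 ± 0.17, and the histone genes Hist1h1t and Hist2h2be at 1.77 ± 0.65 and 0.80 ± 0.42. The cholesterol list was lost without WT fed replicate 2 or 3 or Alkbh5-deficient fed replicate 1, and in the last case its direction turned. Its medians between same-numbered libraries were 0.14, 0.10 and 0.18. With the replicate block it passed (camera adjusted p = 0.0144, and adjusted p = 0.566 with an estimated correlation). The histone list was lost and its direction turned without WT fed replicate 2, and without Alkbh5-deficient fed replicate 1 it passed in the opposite direction (adjusted p = 0.0191). Its direction also turned without replicate 1 of both genotypes. The histone median of same-numbered libraries was -0.18 for replicate 3 against 0.33 and 0.09 for replicates 1 and 2.

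**Figure D3:**
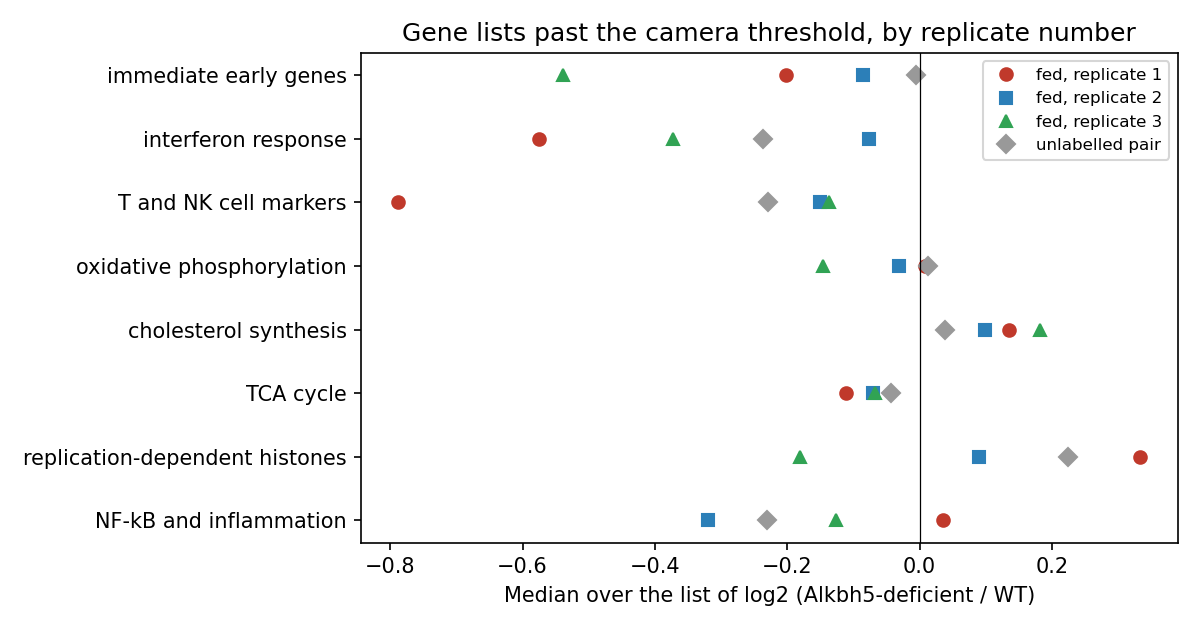
Median over each list's members of the log2 ratio of Alkbh5-deficient to WT libraries, by replicate number for the fed libraries and for the unlabelled pair, for the 8 lists past the camera threshold. Interferon response medians are -0.58, -0.08 and -0.37 for fed replicates 1, 2 and 3 and -0.24 for the unlabelled pair, where the immediate early median is -0.01.

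The other 20 lists did not pass, with adjusted p from 0.0503 to 0.981. These were the lists for monocytes and macrophages, fatty acid oxidation, mast cells with basophils and eosinophils, 2-oxoglutarate metabolism, glycolysis, erythroid cells, B cells, ribosomal proteins, dendritic cells, ATF4 targets, small nucleolar RNAs, stroma and endothelium, stem and progenitor cells, cell cycle, m6A machinery, neutrophils, NRF2 targets, hypoxia response, megakaryocytes and p53 targets. Markers of monocytes and macrophages had 16 of 18 members with a positive value and a median of 0.18, and they passed with the replicate block (camera adjusted p = 0.000543), as did erythroid (0.00147), B cell (0.00535) and mast cell, basophil and eosinophil markers (0.0269), with negative medians. Under the same block these calls were lost, with adjusted p = 0.566 with an estimated correlation for monocyte and erythroid markers and 0.681 for the others, and 0 of the 28 lists passed. B cell marker medians were -1.01 and -0.55 between replicates 1 and 2 and 0.50 between replicates 3. Between replicates 1, 2 and 3 the medians were -0.70, -0.15 and 0.47 for the mast cell list and 0.20, -0.09 and 0.46 for monocytes and macrophages. Those of erythroid markers were all negative, at -0.33, -0.16 and -0.26. Without WT fed replicate 1 the mast cell list had the opposite direction. So did erythroid and B cell markers without WT fed replicate 2 or Alkbh5-deficient fed replicate 1, and in the last case B cell markers passed as higher (adjusted p = 0.00505). Leaving out 1 fed library also leaves the replicate numbers unequal between genotypes. Without replicate 1 of both genotypes the mast cell and B cell lists had the opposite direction, and erythroid markers kept theirs. For small nucleolar RNAs, NRF2 targets, megakaryocytes and p53 targets, the test's direction differed in sign from the median, the mean or both.

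The unlabelled pair, with 1 library per genotype and no replicate check, asked whether these differences were also present without s4U. Alkbh5, the 1 called gene, had the same direction, a share of 100% with an interval of 2.5% to 100%. It is the gene removed by design, so this share does not bear on other genes. Ogdh had 981 counts in the Alkbh5-deficient unlabelled library and 1269 in the WT one, or 107 against 164 CPM, a ratio of 66.3% with a counting interval of 60.9% to 72.1%. Nefh had 68 against 122 counts, a ratio of 47.8% (35.0% to 64.8%). For the 8 lists past the camera threshold, the median log2 ratio in the unlabelled pair was -0.01 for immediate early, -0.24 for interferon response, -0.23 for T and NK cell and -0.23 for NF-kB genes. It was 0.01 for oxidative phosphorylation, -0.04 for TCA cycle, 0.04 for cholesterol synthesis and 0.22 for histone genes. Of 17 genes other than Alkbh5 with an unadjusted edgeR p under 0.01 in the fed libraries and at least 20 counts in the unlabelled pair, 15 (88.2%) had the same direction in that pair. In the other 9 splits of the fed libraries into 3 and 3, the share ran from 0% of 2 genes and 18% of 50 to 75% of 28. The sign of these splits is arbitrary, so a low share there counts like the mirrored high share. Across 13092 genes, which are not independent replicates, the log2 fold changes in the fed libraries and in the pair had a Spearman rho of 0.18. Both unlabelled libraries held RNA of both sexes, and whether they came from the same animals as the fed libraries is not given in the sources used here.

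Fed libraries were compared with unlabelled ones, adjusting for genotype, to see how gene counts differed with s4U feeding. Both unlabelled libraries held RNA of both sexes, while each fed library showed that of a single sex. Feeding therefore cannot be told apart here from a different source or pooling of cells, for the genes and the lists alike. The unlabelled libraries were also closer to each other than any other pair, with a chi-square statistic per gene of 3.12. The 4 genes that passed were all higher in fed libraries and are all annotated as processed pseudogenes, copies of spliced transcripts in the genome, among 14988 genes tested, of which 2933 had an unadjusted edgeR p under 0.05. Gm12715 (chromosome 4, 103563402 to 103564529) averaged 146 ± 13.4 CPM in WT and 145 ± 18.6 CPM in Alkbh5-deficient fed libraries (SD, n = 3 each), against 44.2 and 49.4 CPM in the unlabelled libraries, a log2 fold change of 1.64 ± 0.16 (SE, edgeR adjusted p = 0.0273). Actg-ps1 (chromosome 8, 46228994 to 46230117) had 30.3 ± 5.76 CPM in WT and 25.9 ± 2.83 CPM in Alkbh5-deficient fed libraries, and 54 and 75 counts in the unlabelled ones, a log2 fold change of 1.87 ± 0.23 (SE, edgeR adjusted p = 0.0436). Gm8543 (chromosome 9, 39074102 to 39075735) had 222 counts in the 6 fed libraries and 2 in the unlabelled libraries, a 44.4-fold ratio with a counting interval of 12.2 to 369 (edgeR adjusted p = 0.0418). Hist1h2al (chromosome 13, 51202727 to 51203065) had 433 against 13 counts, a 13.3-fold ratio (7.72 to 25.2, edgeR adjusted p = 0.0418). The closest coding transcript of Gm12715, Actg-ps1 and Gm8543 was that of Actg1, the gamma actin gene, which had a log2 fold change of 0.16 ± 0.20 (SE, edgeR adjusted p = 0.680). That of Hist1h2al was the transcript of the histone gene Hist2h2aa1, which had a log2 fold change of 1.78 ± 0.40 (SE, edgeR adjusted p = 0.165). Identity to the closest transcript was 99.6% for Gm12715, 99.4% for Hist1h2al, 98.3% for Actg-ps1 and 95.6% for Gm8543. Counts of near-identical copies are uncertain, because reads can be assigned to either copy. This covers Gm8543 least, with 45 mismatches over 1130 aligned bases. The count of 4 fell to 0 without either unlabelled library, WT fed replicate 3 or Alkbh5-deficient fed replicate 3, to 1 without WT fed replicate 1, and to 2 without any other fed library. DESeq2 called 591 genes, 324 higher and 267 lower, and most were protein-coding (293 higher and 264 lower), while 24 processed pseudogenes were higher and 0 lower.

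Ogdh and Alkbh5 were not called in the s4U contrast, with log2 fold changes of 0.21 ± 0.17 and 0.20 ± 0.22 (SE, edgeR adjusted p = 0.530 and 0.639). Both signs turned negative without the unlabelled WT library, where the s4U term rests on the Alkbh5-deficient libraries alone.

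By camera with the preset correlation, 9 lists were higher and 1 lower in fed libraries. Trends over all genes differed as well. Deviations from the gene means correlated with transcript length at a Spearman rho of 0.22 and 0.26 in the unlabelled WT and Alkbh5-deficient libraries. In the fed libraries that rho ran from -0.18 to 0.12. A correction for length was not among the alternatives. Ribosomal protein genes had 83 of 85 members with a positive value and a median of 0.41 (adjusted p = 1.26e-18, and adjusted p = 0.437 with an estimated correlation), with Rps6 at 732 ± 2.07 CPM in unlabelled (SD, n = 2) and 1145 ± 124 CPM in fed libraries (SD, n = 6) and Rpl13 at 662 ± 1.81 and 1053 ± 130 CPM. Oxidative phosphorylation genes had 70 of 73 positive and a median of 0.40 (adjusted p = 7.86e-15, and adjusted p = 0.437 with an estimated correlation), with the complex I gene Ndufs7 at a log2 fold change of 0.62 ± 0.16 (SE). TCA cycle genes had 16 of 19 positive and a median of 0.33 (adjusted p = 0.000922, and adjusted p = 0.437 with an estimated correlation), with the succinate dehydrogenase genes Sdhc and Sdhb at 0.68 ± 0.18 and 0.61 ± 0.18. Fatty acid oxidation genes had 16 of 18 positive and a median of 0.33 (adjusted p = 0.000291, and adjusted p = 0.449 with an estimated correlation), with Etfb at 0.65 ± 0.17 and Acads at 0.77 ± 0.20. Glycolysis genes had 17 of 20 positive and a median of 0.47 (adjusted p = 0.000599, and adjusted p = 0.569 with an estimated correlation), while the phosphofructokinase genes Pfkp and Pfkl went opposite ways, at -0.67 ± 0.13 and 0.64 ± 0.17.

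Replication-dependent histone genes had 60 of 66 members positive and a median of 0.35 (adjusted p = 6.81e-08, and adjusted p = 0.569 with an estimated correlation). Hist1h2al, in the list by name but annotated as a processed pseudogene, rose and the other 65 members did not pass over all genes. Immediate early genes had 30 of 35 positive and a median of 0.27 (adjusted p = 0.000122, and adjusted p = 0.455 with an estimated correlation), with Fos at 0.76 ± 0.19 (SE) and Maff at 0.97 ± 0.25. Neutrophil markers had 21 of 21 positive and a median of 0.69 (adjusted p = 0.000291, and adjusted p = 0.569 with an estimated correlation), with the granule protease genes Prtn3 at 0.93 ± 0.23 and Elane at 0.81 ± 0.22. Monocyte and macrophage markers had 17 of 19 positive and a median of 0.55 (adjusted p = 0.0137, and adjusted p = 0.569 with an estimated correlation), with Ctss at 0.78 ± 0.32 and Lyz1, below 1 CPM in both conditions, at 2.45 ± 0.84. Genes of the m6A machinery, its writers, erasers and readers, had 16 of 19 members negative and a median of -0.22 (adjusted p = 0.0384, and adjusted p = 0.449 with an estimated correlation), with the reader Ythdc2 at -0.76 ± 0.20 and the writer subunit Mettl14 at -0.63 ± 0.20.

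None of these list calls held with another treatment of the correlation between genes: 0 of the 28 lists passed with an estimated correlation, and with fry 0 passed, with a smallest adjusted p of 0.0753. Adjusted over the list alone, 5 members of the histone list passed (the processed pseudogene Hist1h2al, and Hist1h3h, Hist2h2aa1, Hist2h2aa2 and Hist2h3c2). So did 5 genes of fatty acid oxidation, 4 of glycolysis, 4 of mast cells, basophils and eosinophils, and 2 each of neutrophils, NRF2 targets and 2-oxoglutarate metabolism, plus Slc7a11 of the ATF4 list and Polk of the p53 list. The remaining 18 lists had camera adjusted p from 0.170 to 0.866. For erythroid, ATF4 and p53 genes the median and the mean differed in sign. Immediate early genes (adjusted p = 0.104), glycolysis (0.0890) and m6A machinery (0.417) no longer passed after GC correction. The m6A list was also lost without the unlabelled WT library or WT fed replicate 1, and the monocyte list without the unlabelled Alkbh5-deficient library. Neutrophil markers had mean log2 CPM of 7.63 and 7.24 in fed replicate 1 of WT and Alkbh5-deficient cells, 6.11 to 6.65 in the other fed libraries and 6.24 and 6.27 in the unlabelled ones.

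**Figure D4:**
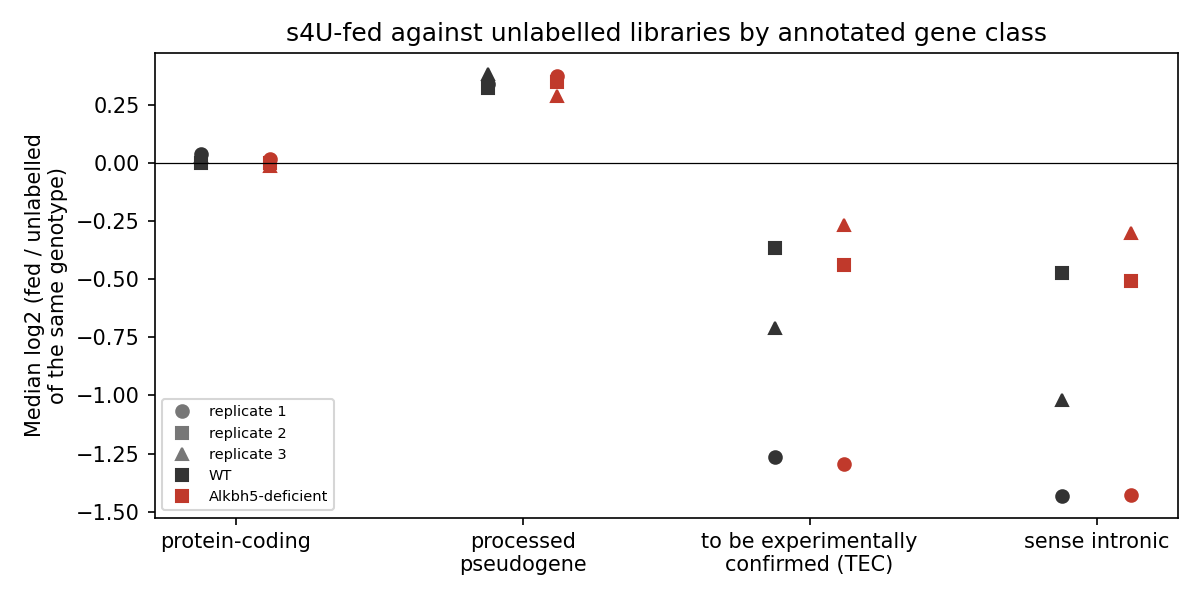
Median log2 ratio of each fed library to the unlabelled library of its genotype, by annotated gene class, with 1 point per fed library. Processed pseudogenes lie between 0.29 and 0.38 in the 6 fed libraries, and sense intronic transcripts between -1.43 and -0.30.

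The interaction asked whether the genotype difference itself differed between fed and unlabelled libraries. With edgeR 0 of 14988 genes passed, and 24 had an unadjusted p under 0.05. DESeq2 also called 0 genes and had 9 at that unadjusted p. For Ogdh the interaction was -0.58 ± 0.32 (SE, adjusted p = 1.00, edgeR), so a difference of the Ogdh change between fed and unlabelled cells was not detectable with 1 unlabelled library per genotype. For Nefh it was -0.11 ± 0.47.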

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

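The tests of the chromosome interval, of neighbouring genes and of the unlabelled libraries' sexes were chosen only after the result was seen. Reads that overlapped several genes, which the comparisons do not use, took a larger share in every fed library than in the unlabelled libraries, at 0.662% for WT and 0.654% for Alkbh5-deficient cells. The share was 0.785%, 0.811% and 0.984% in WT fed replicates 1 to 3 and 0.880%, 0.832% and 0.748% in Alkbh5-deficient fed replicates 1 to 3. No cause was tested.

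Ogdh and Nefh were lower together in Alkbh5-deficient fed libraries. The tables argue against a change of the whole interval, since the 22 tested genes between them had a median log2 fold change of -0.11 ± 0.09 (bootstrap SE), and against GC content, since the weaker change of the pair stayed at -1.08 ± 0.22 (SE) after GC correction with the replicate block. A linked variant of the chromosome carrying the floxed allele stays open: 4.80% of tested genes had as many neighbours within 2 Mb with an unadjusted p under 0.01 as Ogdh, which has 1, Nefh. Whether any sample carried a chromosome recombined over the 54.2 Mb between Ogdh and Alkbh5 was not tested, so such a variant and the loss of ALKBH5 cannot be told apart here. An effect of ALKBH5 on either transcript is a hypothesis that these counts leave open.

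Processed pseudogenes were higher in fed libraries, with a median log2 fold change of 0.39 over 898 genes against 0.04 for protein-coding genes. GC content is argued against, since the difference of the medians was 0.35 both before and after GC correction. A candidate explanation is that converted reads of a parent gene map better to a copy holding C in place of T. Over 782 pseudogenes, however, the rise over the parent did not go with the share of such differences (Spearman rho across genes, which are not independent replicates, 0.0220, bootstrap interval -0.05 to 0.09, permutation p = 0.549). Over the same 782 the rho was 0.0248 for C-to-T differences and 0.23 for identity to the parent. Among the 565 with at least 5 differences, a restriction that was not part of the stated test, rho was 0.09 (permutation p = 0.0365). There C-to-T differences gave a rho of 0.05, and identity to the parent gave a higher rho of 0.26. The mapping of converted reads to copies stays open, and so does library preparation apart from the feeding. RNA of both sexes was in 2 of the 2 unlabelled libraries and 0 of the fed ones, a difference that feeding cannot make. Whether it came from other animals or from a pool of the same ones is not given in the sources used here, so it does not decide between feeding and preparation.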

How the results depend on the processing

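Sample weights, GC correction, removal of ribosomal-repeat genes, removal of both libraries of a pair and DESeq2 with the block were chosen only after the result was seen. The count of 1 gene between genotypes was 2 without the low-count filter and 2 with DESeq2, 6 with DESeq2 and the replicate block, and 9 with voom weights and the replicate block, all of which tested other sets of genes or weighed libraries differently, and it was 1 in the edgeR fit with the replicate block and with each library left out. The cause was not tested. The count of 4 genes for s4U was 37 without the low-count filter, 591 with DESeq2, and 0 to 2 with 1 fed library left out, where fewer samples were compared. Fits within a genotype held 1 unlabelled library each, so their spread came from the fed libraries alone and their counts are not read here. DESeq2 left 17649 genes without an adjusted p. The interaction had 0 genes under each of its 6 alternatives. The 8 lists between genotypes became 0 with an estimated correlation, 11 with the replicate block, 0 with the block and an estimated correlation, and 8 to 13 with 1 library left out. The 10 lists for s4U became 0 with an estimated correlation and 9 to 11 with 1 library left out. In the s4U contrast Alkbh5 was at -0.22 and Ogdh at -0.0704 without the unlabelled WT library, and Ogdh at -0.0699 within Alkbh5-deficient cells. Without the unlabelled WT library only Alkbh5-deficient libraries inform the s4U term. There Alkbh5 had 0, 1 and 1 counts in fed libraries and 1 in the unlabelled one, so its value rests on counts near 0. With 1 library left out Alkbh5 and Ogdh ranged from -0.22 to 0.27 and from -0.0704 to 0.50. The cause of the other shifts was not tested. Where 1 unlabelled library was left out, the other was assumed to vary like the fed groups. Named genes kept their direction under all other settings that gave an adjusted p. Over genotype settings 373 gave the same call for a named gene and 5 a stronger one, and over s4U settings 326 gave the same call, 15 a stronger and 34 a weaker one. The immediate early and interferon lists passed in the same direction under 11 of 11 alternatives with the preset correlation. The share of called genes with the same direction stayed at 100% at a threshold of 0.1, where Alkbh5, the gene removed by design, was again the 1 called gene. With at least 20 counts in both unlabelled libraries no called gene was left, so that alternative gave no value. The low counts of the unlabelled libraries limit the folds of Gm8543 and Hist1h2al.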

Other observations

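The test of unspliced or nuclear RNA was chosen only after the result was seen. Transcripts annotated as sense intronic had a median log2 fold change of -0.80 over 87 genes in the s4U contrast, and transcript models that await experimental evidence (TEC) had -0.70 over 754 genes. After GC correction the medians were -0.50 for sense intronic transcripts and -0.36 for TEC. The TEC medians were -1.27 and -1.29 for fed replicate 1 of WT and Alkbh5-deficient cells, and between -0.71 and -0.27 for the other fed libraries.

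Immunoglobulin variable genes, expressed in B lineage cells, had a median log2 fold change of -0.42 between genotypes over 127 tested genes, with 89 lower. The median was -0.70 between replicates 1 and near 0 between replicates 2 and 3, at -0.05 and -0.01. In the unlabelled pair it was -0.32. The calls that DESeq2 with the replicate block added to Alkbh5 and Ogdh were Ighg2c, Ighv1-81, Ighv6-6 and Hbb-bt, with log2 fold changes of -1.43 ± 0.24, -1.32 ± 0.24, -2.51 ± 0.49 and -1.47 ± 0.32 (SE). The 9 calls of voom with sample weights and the block, chosen after the data were seen, included 1 higher gene, Igkv6-13, at 2.55 ± 0.27 (SE).

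Replicate 1 of both genotypes stood apart from the other fed libraries. B cell markers had mean log2 CPM of 2.67 and 1.65 in these samples, against 3.58 to 4.51 in the other fed libraries, and erythroid markers 4.91 and 4.73 against 5.66 to 6.03, while neutrophil markers lay higher. Small nucleolar RNAs had -0.65 and 0.37 against 1.43 to 2.10, and reads in no gene took 38.3% and 37.6% of counts against 48.9% to 50.3%, both of which go with fewer nuclear RNAs. The tables argue against GC content. The distance between the neutrophil and B cell medians was 3.02 ± 0.49 (bootstrap SE) log2 units before GC correction and 2.97 ± 0.51 after it. The 2 medians had opposite signs, but this cannot decide on fewer unspliced or nuclear RNAs. CPM are relative, and the nuclear share of each list's RNA was not measured. Fewer nuclear RNAs, as a part or the whole of the cause, stay open as a hypothesis. So does a different cell composition of these cultures, and no biological explanation was tested. WT fed replicate 3 also stood apart. Its chi-square statistic per gene against Alkbh5-deficient fed replicate 3 was 40.4, while it was 7.54 between replicates 1 and 6.07 between replicates 2. Its deviations from the gene means correlated with GC content at a Spearman rho of 0.54, against -0.48 to 0.20 in the other libraries. The cause was not tested.

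For chance, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 1 gene and the highest other split 0, so 1 of the 10 splits gave as many. That gene was Alkbh5, which the design removes, so this count does not bear on other genes. For gene lists, 7 of the 10 splits gave as many as the real 8, and the highest other gave 14. The 3 splits that gave 14 lists put both replicate 1 libraries on the same side, which points to a structure of the samples by replicate number. Among the 4 splits that part all 3 pairs, the highest other count was 8 lists, equal to the real one, and the replicate block gave 11, or 0 with an estimated correlation.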
